A study of Mus musculus with 3 samples.

How the data were processed

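Single-cell RNA sequencing was done on TdTomato-positive cells sorted from mouse sciatic nerve, in which a tamoxifen-inducible Cre driven by Pdgfrb had switched on the TdTomato reporter. The 3 libraries were intact nerve, the bridge region at day 7 after injury and the bridge region at day 21, with 1 library in each group. Per the labels' protocols, nerves were pooled, digested with collagenase and hyaluronidase, and sorted by TdTomato, and myelin was removed with beads for the intact sample alone, so the bead step and the group cannot be separated.

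The deposited matrices held whole-number UMI counts per gene and barcode, made with Cell Ranger per the submitters' processing notes, which name versions 6.1.2 and 3.0.2 without saying which library each was used for. The notes also name Seurat 4.0.1 and the builds mm10 and GRCm38. Cell filters were not given in the sources used here. The authors' cell metadata, per the file headers, gave each cell its library and 1 of 6 classes. Of the 7235 cells it listed, 7234 were found among the 14703 barcodes, and 1 cell of the day 21 library was not found. The annotated cells had at least 2012 UMIs and at least 1001 genes, with at most 9.70% mitochondrial UMIs, and the other 7469 barcodes had no class. Of those, 4139 had at least 2000 UMIs, at least 1000 genes and under 10% mitochondrial UMIs.

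Gene positions were taken from GENCODE M21 on the same assembly. Of 465 genes looked up by identifier, 464 had a position and 420 of these carried the same identifier version as the matrices. TdTomato was the 1 without a position. Positions are printed below for genes of the same version.

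UMIs were summed over the annotated cells of each library and expressed as CPM, the unit that the text below uses. Each gene's count was scaled to the summed UMIs of those annotated cells. Where a value covers a class, a cluster or other barcodes, it was scaled to the summed UMIs of these. Log2 ratios of CPM were formed after adding 0.5 counts to each sum. Each gene's ratio has an exact conditional binomial 95% interval, each CPM an exact Poisson interval and each share of cells an exact Clopper-Pearson interval, and these cover counting error only. Where a library had 0 counts of a gene, the ratio was computed against 3 counts and is given as a bound. No test was made, since cells are not replicates and each group was 1 library. Library totals over every barcode, with or without a class, were 11509106 UMIs for intact nerve, 58155334 for day 7 and 51898719 for day 21. The CPM of annotated cells was not scaled to these totals.

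Before the data were examined, 15 marker lists and 23 process lists were fixed, along with the rule for naming genes. The marker lists covered endoneurial, epineurial, perineurial and injury mesenchymal cells, pericytes, vascular smooth muscle, endothelium, Schwann cells, myeloid cells, lymphocytes, neutrophils and mast cells, adipocytes, skeletal muscle, tenocytes and chondrocytes, and erythroid cells. The process lists covered the cell cycle, fibrillar and interstitial matrix, basement membrane, contractile genes, TGF-beta response, Wnt targets, Wnt ligands, junction and barrier genes, angiogenic factors, guidance genes, hypoxia and glycolysis, neurotrophic factors, chemokines and cytokines, complement, interferon response, matrix proteases, the hedgehog pathway, retinoid metabolism, the imprinted growth network, lipid handling, immediate-early genes, the Notch pathway and PDGF receptors. Of all list symbols, 5 were left out: Ccn1, Ccn2, Figf and Gtl2, for which the matrices use other symbols, and Aldoa, whose symbol occurs more than once. A list is summarised by the median log2 ratio of its measured members, those with more than 3 counts in either library, with an exact order-statistic 95% interval over members. Its percentile is taken among 10000 random lists of the same size, with each member drawn from the 100 genes nearest in mean abundance, and describes these libraries only.

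Named genes are the 10 with the largest ratio in each direction per comparison. They needed at least 50 CPM and a UMI in at least 10% of cells in the higher library. Mitochondrial, ribosomal, haemoglobin, numbered-clone, Xist, Y-linked and transgene features were left out, as were markers of non-mesenchymal types, read, after the rule was fixed, as endothelial, Schwann, myeloid, lymphocyte, neutrophil and mast cell, adipocyte, skeletal muscle and erythroid. Markers of pericytes, vascular smooth muscle, tenocytes and chondrocytes were therefore kept, and Acta2 is 1 of them. From each list, up to 4 members with the largest absolute ratio and at least 20 CPM were eligible, and Pdgfrb and Pdgfra were always named. Within a class the 3 largest in each direction were taken, for classes with at least 100 cells in both libraries. That part was narrowed to day 21 against intact after cluster membership had been seen, because at day 7 a cluster with injury markers held 210 of 241 perineurial cells, another held 310 of 676 epineurial cells, and the former also held 88 of 255 endoneurial cells. Other genes named within a class are list members picked as examples after their values were seen.

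For shares of cells with UMIs of a list, each cell was thinned to 3500 UMIs, and shallower cells were left out, 225 in intact nerve, 43 at day 7 and 267 at day 21. A cycling cell had at least 2 UMIs over the cell cycle list. Doublets were scored with scrublet, which marked 32 intact barcodes, 0 at day 7 and 5 at day 21, and is taken not to have worked for the bridge libraries. No cell was removed as a doublet in the values reported. Cells were also clustered with leiden, and clusters were named from the fixed markers.

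The ratio and list steps were run on simulated counts with 200 genes changed by known folds. Each gene was drawn independently from a Poisson distribution, the model that the intervals assume. Coverage near 95% was thus given in advance, and spread between cells, co-regulation and class mixture were not simulated. Intervals covered the true ratio for 96.0% of changed genes for day 7 against intact (19013 genes), 95.5% for day 21 against intact (18872 genes) and 95.0% for day 21 against day 7 (19589 genes). Of 200 unchanged lists of 15 genes, 6.50%, 3.00% and 2.00% fell outside the central 95% of random lists in these comparisons.

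The alternatives tried were every barcode, size factors by median of ratios, equal weight per cell, thinned cells, a total without mitochondrial, ribosomal and immediate-early genes, called doublets left out, 1 class mixture for both libraries, and list members under 5 CPM left out. Classes from clustering, shallow cells left out, other UMI minimums and unthinned counts were tried for shares. Size factors moved the median ratio of all genes by 0.10 for day 7 against intact, by -0.03 for day 21 against intact and by -0.13 for day 21 against day 7. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9 were used.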

Results

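The series profiled Pdgfrb-lineage mesenchymal cells of the mouse sciatic nerve by droplet single-cell RNA sequencing, in intact nerve and in the bridge that forms across an injury, at day 7 and day 21. There were 3 libraries, 1 per group, so no difference below has a replicate check, and intervals cover counting error only. After the authors' annotation the libraries held 1343 cells of intact nerve with a median of 5667 UMIs per cell, 1780 cells at day 7 with 19316 and 4111 cells at day 21 with 7442. The annotated cells carried 8371421, 36169912 and 33683464 UMIs in that order. The authors' series title concerns wound angiogenesis and mesenchymal barrier compartments in the regenerating nerve, and the comparisons below set each bridge library against intact nerve and against the other.

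The authors' class names were tied to tissue layers by the fixed markers. MES_ENDO cells had the highest level of 7 of 8 endoneurial markers, MES_EPI cells of 9 of 11 epineurial markers and MES_PERI cells of 8 of 8 perineurial markers, and MES_EPI-diff cells of 6 of 8 injury markers. They are called the endoneurial, epineurial, perineurial and MES_EPI-diff classes here. The meaning of MES_DIFF was not given in the sources used here. MES_DIV held cells rich in cell cycle transcripts and is called the dividing class. The marker levels were means over libraries with enough cells of a class. Intact nerve, with 1 MES_EPI-diff and 7 dividing cells, was left out for these classes only. The injury marker count for MES_EPI-diff thus mixes class with library.

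The makeup of the sorted cells differed between the libraries, with endoneurial and epineurial cells most frequent in intact nerve and perineurial cells at day 21. Endoneurial cells were 49.4% of intact cells (95% interval 46.7 to 52.1), 14.3% at day 7 (12.7 to 16.04) and 11.8% at day 21 (10.9 to 12.9). Perineurial cells, which in intact nerve form the sheath around each fascicle, were 8.64% of intact cells (7.19 to 10.3), 13.5% at day 7 (11.98 to 15.2) and 50.3% at day 21 (48.8 to 51.9). Epineurial cells made up 40.2%, 38.0% and 24.98%, and without cells under the thinning depth intact nerve had 45.1% epineurial and 44.3% endoneurial cells. MES_DIFF cells were 1.19% of intact cells, 17.3% at day 7 and 9.41% at day 21. MES_EPI-diff cells were 0.0745%, 5.28% and 0.535%, and dividing cells 0.521%, 11.6% and 2.89%. The day 7 shares depended on the source of the classes, since clustering with the same markers gave 1.40% perineurial, 21.1% epineurial and 8.65% endoneurial cells, and 210 of the 241 day 7 perineurial cells lay in a cluster led by Aldh1a3, Areg and Spp1. Over every barcode, with other cell types in the total, clustering gave 8.12% perineurial cells in intact nerve and 33.2% at day 21. Endoneurial cells were then 40.2% in intact nerve and 6.64% at day 21. The sort, the bead step used for intact nerve alone and dissociation can each set such shares.

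**Figure D1:**
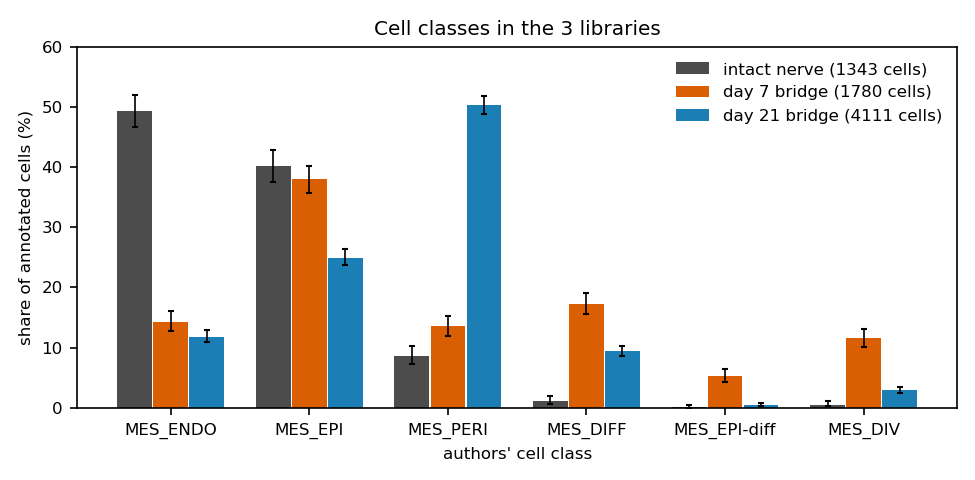
Share of annotated cells (percent, vertical axis) in each of the authors' 6 classes (horizontal axis) for the 3 libraries, with exact 95% binomial intervals as bars. The perineurial class reaches 50.3% in the day 21 library against 8.64% in intact nerve.

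At day 7 the sorted cells carried more transcripts of injury markers and cell cycle genes than intact cells. They carried fewer transcripts of some of the genes that lead in intact endoneurial and epineurial cells. Tnc, which encodes the matrix protein tenascin-C, was at 745 CPM against 2.99, a 245-fold higher level (interval 169 to 386). Areg, encoding the EGF receptor ligand amphiregulin, was at 52.5 CPM against 0.119, a ratio of 293 that rests on 1 intact count (78.8 to 17380). Cthrc1 was 37.5-fold higher (32.6 to 43.6) and Ptn, which encodes the heparin-binding growth factor pleiotrophin, 62.4-fold higher (52.0 to 76.4). In the other direction Inmt was 200-fold lower (164 to 249), a log2 ratio of -7.645 that was -6.86 with each cell weighted alike, and Gsn, encoding the actin-severing protein gelsolin, was at 525 CPM against 18320, 34.9-fold lower (34.4 to 35.5).

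Areg (ENSMUSG00000029378.5) lies on chromosome 5 from 91139599 to 91148432 of mm10, Tnc (ENSMUSG00000028364.15) on chromosome 4 from 63959785 to 64047015, Ptn (ENSMUSG00000029838.11) on chromosome 6 from 36714929 to 36810220, and Inmt (ENSMUSG00000003477.5) on chromosome 6 from 55170626 to 55175043. The other genes named as highest at day 7 were the replication-dependent histones Hist1h1b (244-fold), Hist1h2ae (43.0-fold) and Hist1h2ap (41.7-fold), the replication factor gene Pclaf (44.5-fold), Ddah1 (109-fold) and C1qtnf3 (44.4-fold). Those named as lowest were the complement gene C7 (61.5-fold), Smpd3 (50.9-fold), Enpp2, which encodes autotaxin (38.5-fold), Adh1 (29.6-fold), Spock2 (23.8-fold), Vit (23.3-fold), Crispld2 (21.9-fold) and Pcolce2 (21.1-fold). With each cell weighted alike the log2 ratio was 6.18 for Pclaf, -4.99 for Smpd3, -4.28 for Adh1 and -3.76 for Pcolce2, in place of 5.48, -5.67, -4.89 and -4.40.

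Among the fixed lists, all 8 injury markers were more than 2-fold higher at day 7, with a median log2 ratio of 4.05 (2.41 to 7.93) above all 10000 random lists, and Lrrc15 was at 47.5 CPM against 0.478 and Postn at 3278 against 184. All 20 measured cell cycle genes were more than 2-fold higher (median 2.93, 2.46 to 3.25). In the imprinted growth network, 8 of 11 members were more than 2-fold higher (median 1.91), with Mest at 846 CPM against 54.6 and H19 at 882 against 84.5. The matrix list had a median of 0.94 (0.47 to 1.34), with 11 of 22 members more than 2-fold higher, among them Col12a1 (3.34), and 2 lower, among them Dcn (-2.60), while its summed level was 57998 CPM against 57639. TGF-beta response genes had a median of 1.28 (-0.65 to 2.00), and neurotrophic factors a median of 1.00 (-0.56 to 1.91), with Mdk at 2.41 and Igf1 at 1296 CPM against 457. Contractile genes had a median of 0.89 (-0.74 to 1.52), with Actn1 at 1.97 and Mylk at 15.1 CPM against 60.1, and vascular smooth muscle markers had a median of 0.72 in the same cells. The contractile median was -2.78 over every barcode, and the unclassed barcodes of intact nerve held vascular smooth muscle markers at 22457 CPM against 297 in its annotated cells.

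The list medians of the intact layer markers stood lower at day 7, although the upper ends of their intervals were positive. The perineurial list had a median of -2.07 (-3.07 to 0.25), with 6 of 8 members more than 2-fold lower, among them Lypd2 and Itgb4 (both -3.07). The endoneurial list was at -1.26 (-2.28 to 3.25), with Meox1 at -1.76 while Wif1 was at 3.25, and the epineurial list at -0.97 (-2.05 to 0.16), with Comp at -2.05. Complement genes had a median of -1.29 (-2.52 to -0.51), with C3 at -2.52, and lipid handling genes a median of -1.39 (-2.34 to 0.18), with Apoe at -2.43 and Apod at -2.34. Basement membrane genes were at -0.35 (Lamb2 -1.79) and immediate-early genes at -0.49 (Egr1 -1.05). These medians lay outside the central 95% of random lists. Notch genes had a median of 0.56 (Notch2 -0.85), which was -0.16 with 1 class mixture and -0.86 over every barcode. The lists inside the central 95% were Wnt targets (-0.33), Wnt ligands (-0.43), junction genes (-0.37), angiogenic factors (-0.12), guidance genes (0.10), hypoxia (-0.24), chemokines (0.14), interferon response (0.06), proteases (0.32), hedgehog (-0.04) and retinoid genes (0.49). The cell cycle median was 0.11 with 1 class mixture, which fixes the share of the dividing class itself. It was 2.94 without the dividing class, an alternative chosen after seeing the data. The mixture had no cell minimum, so its values against intact nerve rest in part on few intact cells. These were 7 dividing, 16 MES_DIFF and 1 MES_EPI-diff cells.

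At day 21 some perineurial and barrier transcripts were more abundant in the sorted cells than in intact nerve, and injury markers stood between their intact and day 7 levels. Lgals7, which encodes galectin-7, was at 244 CPM against 1.07, a 216-fold higher level (120 to 498). Crabp2, encoding a retinoic acid binding protein, was 21.1-fold higher (17.4 to 26.2), Spink1 20.9-fold (15.1 to 30.9, a log2 ratio of 4.38 that was 5.06 with each cell weighted alike) and Ptn 25.1-fold (20.8 to 30.7). Of the perineurial markers, Cldn1, which encodes the tight junction protein claudin-1, was at 581 CPM against 89.8 and Krt19 at 184 against 29.3. Inmt was 24.9-fold lower (23.1 to 27.0), and A2m was 19.7-fold lower (16.4 to 24.0).

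Lgals7 (ENSMUSG00000053522.11) lies on chromosome 7 from 28863853 to 28866284 of mm10. The other genes named as highest were Tnfsf8 (20.3-fold), the aryl hydrocarbon receptor gene Ahr (11.1-fold), Sbspon (10.2-fold), the nuclear receptor gene Nr4a2 (9.98-fold), Moxd1 (9.12-fold) and Dusp5 (9.06-fold). The others named as lowest were Angptl7 (14.1-fold), Crispld2 (14.0-fold), C7 (13.5-fold), Adh1 (12.9-fold), Acta2, which encodes smooth muscle actin (9.47-fold), Plac9b (9.43-fold), Pcolce2 (9.24-fold) and Enpp2 (8.87-fold). Of the 839 intact Acta2 counts, 394 came from the 116 perineurial cells, and 12 of these cells held 78.7% of the 394.

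Among the lists at day 21, perineurial markers had a median log2 ratio of 0.71 (-1.78 to 3.19) against intact, 3 of 8 more than 2-fold higher and 2 lower, with Moxd1 at 3.19, Cldn1 at 2.69 and Krt19 at 2.65 but Msln at -1.78. With 1 class mixture for both libraries this median was -1.39, and that of the junction and barrier list was -0.50 in place of 0.30 (-0.19 to 1.30). In the junction list 6 of 20 members were more than 2-fold higher and 2 lower, and Ocln stood at 2.80 and Gjb2 at 4.78, and Jam2 at -2.23. Injury markers had a median of 1.51 (0.27 to 3.74), with Postn at 2.78, and cell cycle genes 1.58 (1.01 to 1.82), which was 0.05 with 1 class mixture and 0.50 without the dividing class. Hedgehog genes had a median of 0.82 (0.11 to 1.57), with Hhip at 1.57. Notch genes were at 0.74 (Hes1 1.01), which was -0.10 over every barcode, neurotrophic factors at 0.37 and the matrix list at 0.32.

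Lower at day 21 were contractile genes (median -1.04, -3.14 to 0.38), with Tagln at -1.19 and the vascular smooth muscle markers at a median of -1.65 in the same cells, chemokines (-0.79, -1.32 to -0.03), with Cxcl12 at -1.90 and Il33 at -1.41, and complement genes (-0.92, -2.77 to -0.26), with C3 at -2.77 and C4b at -1.70. Endoneurial markers had a median of -0.998 (Spp1 -2.19) and epineurial markers -0.95 (Comp -4.08). Retinoid genes had a median of -0.55, although Crabp2 was at 4.40 and Cyp26b1, which encodes a retinoic acid hydroxylase, at -3.00. Interferon response genes were at -0.36, lipid handling genes at -0.42 and proteases at -0.21. The protease median was 0.30 with 1 class mixture and the lipid median 0.003 over every barcode. Inside the central 95% of random lists were basement membrane (0.01), TGF-beta response (0.22), Wnt targets (0.10), Wnt ligands (-0.21), angiogenic factors (-0.12), guidance (-0.11), hypoxia (0.07), imprinted (0.21) and immediate-early genes (0.04). Within these lists Wnt6 was at 2.11 and Fgf1 at 2.77.

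**Figure D2:**
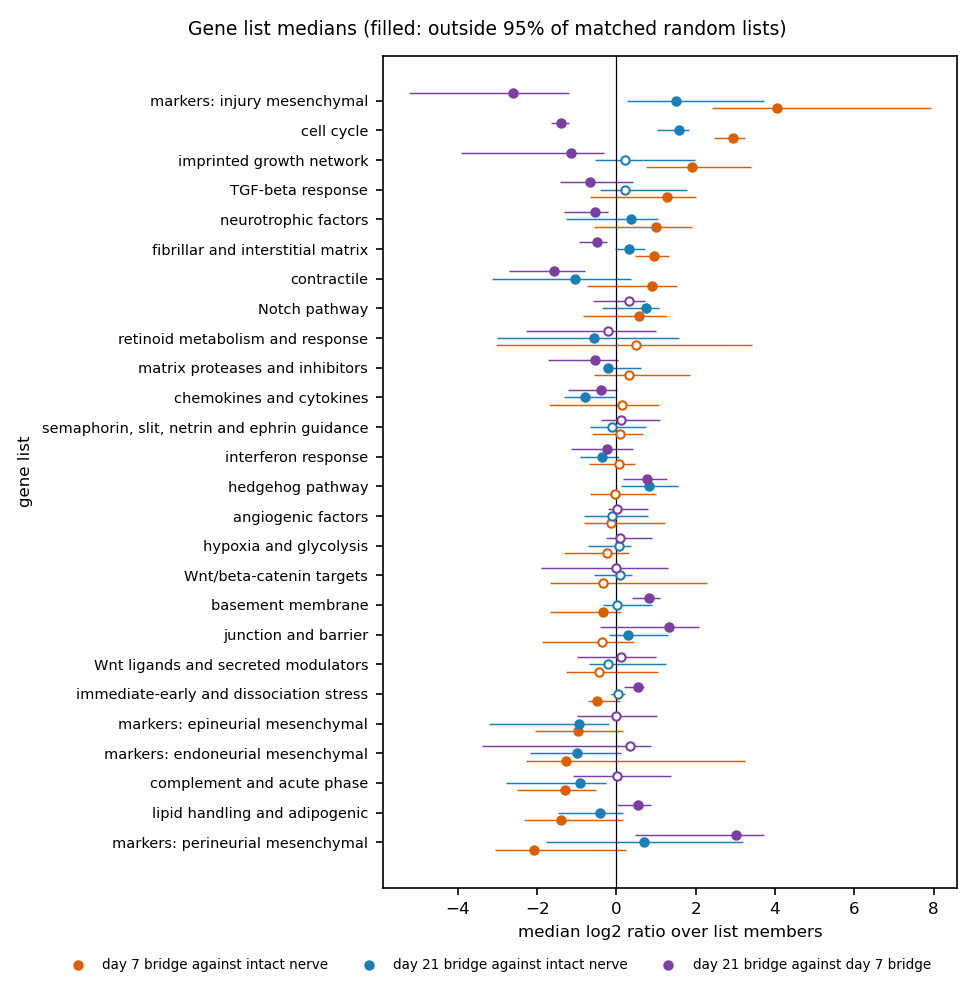
Median log2 ratio (horizontal axis) of the fixed gene lists (vertical axis) in the 3 comparisons, with order-statistic 95% intervals over list members as lines and filled points for medians outside the central 95% of matched random lists. Perineurial markers are at -2.07 for day 7 and 0.71 for day 21 against intact nerve.

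Between the bridge libraries, day 21 cells had more perineurial and basement membrane transcripts and fewer injury, contractile and cell cycle transcripts than day 7 cells. Spink1 was 18.6-fold higher at day 21 (15.9 to 21.99), Krt19 13.1-fold (11.99 to 14.4), Cav1, which encodes caveolin-1, 14.3-fold (13.6 to 15.1) and Itgb4, encoding the integrin beta-4 chain of hemidesmosomes, 11.9-fold (10.96 to 13.03). Tnc was 18.4-fold lower (17.4 to 19.4), Areg 28.8-fold (22.5 to 38.1), Acta2 17.7-fold (15.9 to 19.8) and the imprinted RNA H19 15.2-fold (14.6 to 15.96). The others named as higher were Adamtsl3 (18.1-fold), Sult1a1 (15.2-fold), Lmo7 (13.7-fold), Myoc (12.4-fold), Moxd1 (11.9-fold) and the transporter gene Slc6a13 (11.7-fold). The others named as lower were C1qtnf3 (15.1-fold), Cthrc1 (10.9-fold), Spp1, which encodes osteopontin (10.5-fold), Ddah1 (9.29-fold), the retinaldehyde dehydrogenase gene Aldh1a3 (8.11-fold) and Arl4c (6.21-fold).

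The perineurial list had a median of 3.02 (0.48 to 3.71) for day 21 against day 7, with 6 of 8 members more than 2-fold higher, and the junction list 1.33 (-0.41 to 2.09), with Ocln at 4.19 and Slc2a1, which encodes a glucose transporter, at 2.79. Basement membrane genes had a median of 0.81 (0.40 to 1.10), with Col4a1 at 1.10 and Lamb2 at 1.44. Hedgehog genes were at 0.77 (Ptch1 1.29), lipid genes at 0.55 (Lpl 2.04) and immediate-early genes at 0.55 (Socs3 1.63). Injury markers had a median of -2.60 (-5.23 to -1.19), with 8 of 8 more than 2-fold lower, contractile genes -1.59 (-2.70 to -0.79), which was -0.70 over every barcode, with vascular smooth muscle markers at -2.12 (8 of 8 more than 2-fold lower), and cell cycle genes -1.40 (-1.64 to -1.21), which was -0.01 with 1 class mixture and -1.68 without the dividing class. Imprinted genes were at -1.15, TGF-beta response at -0.67, proteases at -0.55 (Timp1 -2.22), neurotrophic factors at -0.53, the matrix list at -0.49 and chemokines at -0.39 (Cxcl2 -2.03). Interferon genes were at -0.25, which was 0.14 over every barcode. Endoneurial markers (0.35), epineurial markers (-0.02), Wnt ligands (0.12), Wnt targets (0.00), angiogenic factors (0.01), guidance (0.13), hypoxia (0.09), complement (0.01), retinoid (-0.22) and Notch genes (0.31) lay inside the central 95%.

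Within classes, day 21 cells were compared with intact cells of the same class. In the epineurial class Ptn was at 726 CPM against 16.5, 43.8-fold higher (34.5 to 57.2), Cldn1 29.5-fold (18.1 to 56.0) and Ahr 21.8-fold (13.4 to 41.5). Cldn1 was at 108 CPM there against 1090 in day 21 perineurial cells, so free RNA is not excluded for it. The chemokine gene Cxcl13 was 43.8-fold lower (34.9 to 56.5), Comp 18.1-fold (13.4 to 25.5) and Inmt 16.7-fold (15.4 to 18.1). In the endoneurial class Lgals7 was at 52.4 CPM against 0 counts, at least 60.6-fold higher, although 25 and 11 of these 487 cells lay in perineurial-like clusters led by Lgals7 and the perineurial class held it at 444 CPM, so such cells or free RNA are not excluded. The lipid exporter gene Abca1 was 23.9-fold higher (12.2 to 64.2) and Col14a1 21.8-fold (14.4 to 36.2). Rbp4 was 23.4-fold lower (16.8 to 34.6), Crispld2 9.95-fold (9.07 to 10.96) and Hsd11b1, which encodes a glucocorticoid-activating enzyme, 8.39-fold (6.18 to 11.9). In the perineurial class Lgals7 was 92.1-fold higher against 3 intact counts (36.8 to 521). Mndal and Ptn rested on 1 intact count each, with ratios of 27.7 (7.43 to 1643) and 25.9 (6.95 to 1536), and Ptn, at 53.5 CPM there against 726 in epineurial cells, is not told apart from free RNA either. Acta2 was 136-fold lower (103 to 186), with 12 of the 116 intact cells holding 78.7% of its UMIs and the other 104 at 134 CPM, Rbp4 74.6-fold (51.2 to 114) and Thsd4 45.1-fold (27.7 to 77.7).

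Junction and barrier genes had median log2 ratios of 0.60, 0.62 and -0.79 (-1.72 to 0.31) in the endoneurial, epineurial and perineurial classes. In the perineurial class Itgb4 was at -1.84, Slc2a1 at -1.28 and Abcb1a at -3.14, while Cldn1 was at 0.31. Perineurial cells were 50.3% of the day 21 library, so free RNA is not excluded for the endoneurial and epineurial medians. For the endoneurial median, the 25 and 11 cells in perineurial-like clusters are not excluded either. Matrix genes had medians of 0.36, 1.12 and 0.94 in these 3 classes, with Col3a1 at 1.34 in epineurial and 1.83 in perineurial cells. Contractile genes had medians of -0.69, -0.48 and -2.13. Basement membrane genes were at -0.02, 0.51 and 0.50. Complement genes were at -1.56 in the epineurial class (C3 -2.30), and imprinted genes at 1.15 there (Mest 3.53, Dlk1 4.13). Hedgehog genes had medians of 0.90 in endoneurial and 1.06 in epineurial cells, with Ptch1 at -0.43 in the former and 1.83 in the latter. Wnt ligands (1.35, with Wnt6 at 2.60) and angiogenic factors (0.77) were higher in endoneurial cells. Wnt6 was among the leading genes of a perineurial-like cluster that held 25 of the 487 day 21 endoneurial cells. Such cells or free RNA are therefore not excluded for it. Immediate-early genes had a median of 1.61 in perineurial cells (Fos 2.06), against 0.06 and 0.27 in endoneurial and epineurial cells. The clusters holding most cells of each class differed between the libraries: 656 of 663 intact endoneurial cells lay in a cluster that held 59 of the 487 at day 21, of which 389 lay in another, and of 116 intact perineurial cells 82 lay in a cluster that held 41 of the 2069 at day 21.

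**Figure D3:**
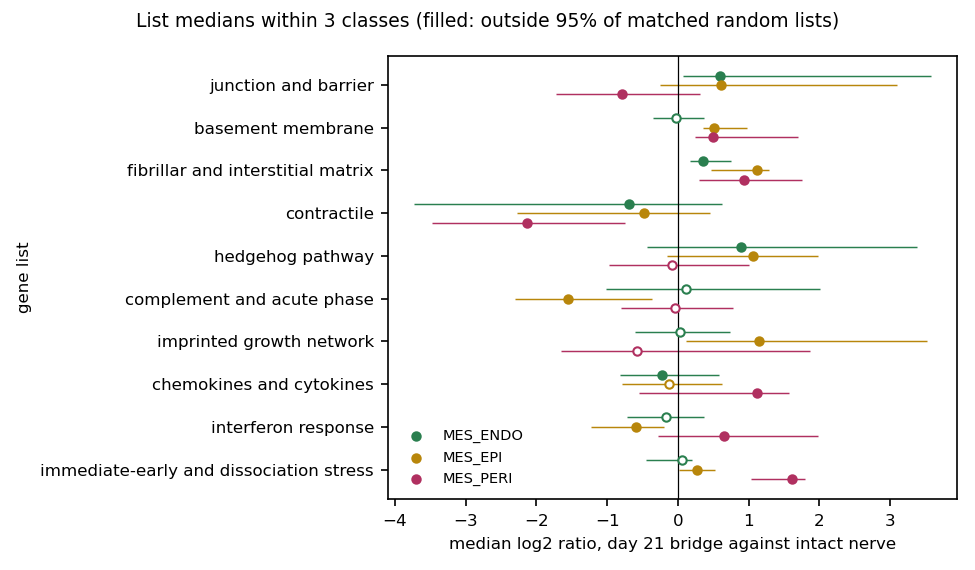
Median log2 ratio of day 21 bridge against intact nerve (horizontal axis) of selected gene lists (vertical axis) within the endoneurial, epineurial and perineurial classes, with order-statistic 95% intervals over members as lines and filled points for medians outside the central 95% of matched random lists. Junction and barrier genes are at 0.60, 0.62 and -0.79 in that order.

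Cycling cells were most frequent at day 7. After thinning, 17.7% of day 7 cells had at least 2 UMIs over the cell cycle list (15.9 to 19.6), against 1.61% of intact cells (0.957 to 2.53) and 3.98% of day 21 cells (3.38 to 4.65). The unthinned shares were 49.2%, 3.43% and 7.49% and carry the difference in depth. At day 7, 190 of 200 dividing cells and 11.7% of MES_DIFF cells passed this limit, against 13.8% of MES_EPI-diff, 9.17% of endoneurial, 8.19% of perineurial and 4.07% of epineurial cells. For the epineurial class the median depth before thinning was 19883.5 UMIs, against 24149.5 in the dividing class. At day 21 it was 99 of 116 dividing cells, 2 of 22 MES_EPI-diff cells, 2.64% of MES_DIFF, 2.15% of endoneurial, 1.20% of epineurial and 1.07% of perineurial cells. Of the dividing class, 30 of 206 cells at day 7 and 50 of 119 at day 21 lay in a Schwann-like cluster, and 32 and 18 in an unnamed cluster with pericyte markers. Without these clusters the shares were 15.2% at day 7 and 2.70% at day 21, an alternative chosen after seeing the data.

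The receptor genes that mark this lineage stood lower in the bridge. Pdgfrb was at 363 CPM in intact nerve (350 to 376), 126 at day 7 (123 to 130) and 171 at day 21 (167 to 176), and Pdgfra at 842, 236 and 287 CPM. The 2 genes had list medians of -1.68 for day 7 and -1.32 for day 21 against intact, and 0.36 between the bridge libraries. TdTomato, the sorted reporter, was at 68.0, 73.8 and 62.5 CPM.

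**Figure D4:**
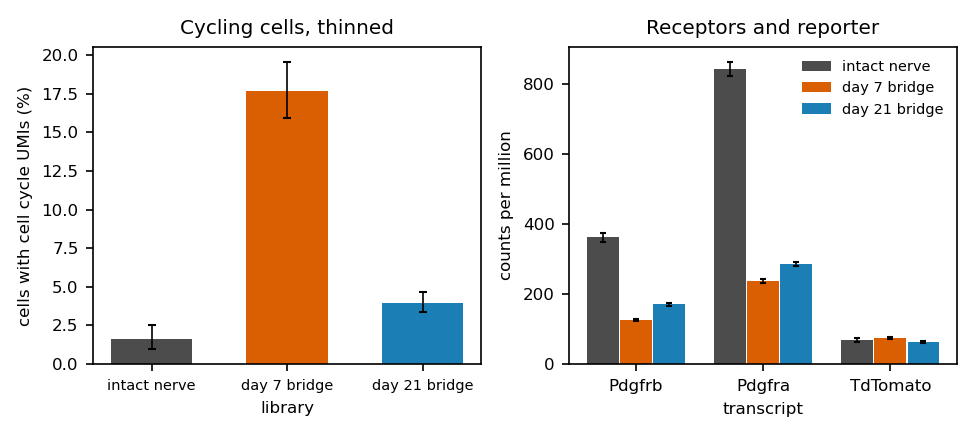
Left, share of cells (percent, vertical axis) with at least 2 cell cycle UMIs after thinning in each library (horizontal axis), with exact 95% binomial intervals. Right, CPM (vertical axis) of Pdgfrb, Pdgfra and TdTomato (horizontal axis) in each library, with exact 95% Poisson intervals, where Pdgfrb is at 363 in intact nerve and 126 at day 7.

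Markers of other cell types were measured in the annotated cells as summed CPM for intact nerve, day 7 and day 21. Schwann markers were at 46.8, 69.2 and 294. Endothelial markers were at 39.3, 82.9 and 157, although Cdh5, at 32.0, 47.6 and 136, is also carried by perineurial cells here (267 CPM at day 21). Pericyte markers were at 326, 257 and 475 (Rgs5 at 5.02, 73.0 and 23.2), and vascular smooth muscle markers at 297, 466 and 92.1. Myeloid markers were at 8.48, 44.8 and 31.0, lymphocyte markers at 0.119, 1.77 and 1.72, adipocyte markers at 8.003, 2.60 and 3.92, skeletal muscle markers at 16.2, 6.94 and 9.23, and erythroid markers at 11.3, 0.968 and 1.63. Tenocyte and chondrocyte markers were at 57.7, 72.5 and 48.9. Neutrophil and mast cell markers were at 1.67, 0.221 and 72.3. At day 21, 2952 of the 2972 UMIs of the mast cell genes Cma1, Mcpt4, Tpsb2 and Cpa3 came from 1 cell of 32823 UMIs.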

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

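The differences between groups listed here were not tested, since each group was 1 library, and they are given because the direction differed between time points or classes. Perineurial markers had a median log2 ratio of -2.07 at day 7 and 0.71 at day 21, each against intact nerve, and the day 21 value was -1.39 with 1 class mixture for both libraries. Contractile genes were at 0.89 and -1.04 in the same comparisons, and the day 7 value was -2.78 over every barcode.

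Within classes, for day 21 against intact nerve, junction and barrier genes were at 0.60 in endoneurial, 0.62 in epineurial and -0.79 in perineurial cells. Free RNA is not excluded for the endoneurial and epineurial values, nor are perineurial-like cells for the endoneurial value. Retinoid genes were at 0.52, -0.39 and -0.64 in endoneurial, epineurial and perineurial cells, and the endoneurial value was -0.0703 with thinned cells. Chemokines and cytokines were at -0.23 in endoneurial and 1.12 in perineurial cells, and interferon response genes at -0.59 in epineurial and 0.65 in perineurial cells.

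The reporter was also found in barcodes to which the authors gave no class, above what a count of 0 allows over the 3 libraries together, a limit that free RNA would pass as well. TdTomato was at 79.2 CPM in Schwann-like barcodes, 171 in pericyte-like, 113 in vascular smooth muscle-like, 15.8 in endothelial-like and 17.4 in myeloid-like barcodes. The endothelial-like and myeloid-like levels are not told apart from background, and the others lie above them. In intact nerve alone it had 0 counts in 28 endothelial-like and 5 Schwann-like barcodes and 1 count in 2 myeloid-like barcodes.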

How the results depend on the processing

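A list median was counted as moved if it left its interval over list members. A change of sign was counted as reversed only for medians outside the central range of random lists. The intervals can be wide, as for retinoid genes for day 7 against intact (-3.05 to 3.42). The totals also include settings that change little, such as leaving out called doublets. High counts of unchanged values are thus largely built in and tell little. Counted as neither moved nor reversed were 263 of 270 values for day 7 against intact. The counts were 256 of 270 for day 21 against intact and 259 of 270 for day 21 against day 7. These counts do not show that medians near 0 kept their direction. Size factors shifted day 21 against day 7 ratios by -0.13, which turns medians such as complement (0.01) and angiogenic factors (0.01) negative. No list was counted as reversed there. Of 120 named gene values none reversed and 33 moved, and 6 differed by over 1.5-fold, at most by 0.787 log2 units for Inmt. Named genes were chosen for the largest ratios, so the lack of reversals follows from the choice and tells little. Within classes 104 of 105 list values were counted as neither moved nor reversed. Leaving out list members under 5 CPM, the most abundant gene families or the 5% highest doublet scores moved none of the list medians over all annotated cells out of its interval. Leaving out called doublets tells nothing for the bridge, where 0 and 2 annotated cells were called. No paired analysis was possible because each group was 1 library and the labels give no pairing. Depth limits the genes with few intact counts, since the intact library held 8371421 annotated UMIs. Leaving out the dividing class, the 5% of cells with the highest doublet scores, or the Schwann-like and pericyte-marker clusters were alternatives chosen after seeing the data. Except for the class mixture and the cells added by using every barcode, which act by construction, the cause was not tested.

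With 1 class mixture for both libraries, medians for day 21 against intact were -1.39 for perineurial markers, -0.50 for junction genes and 0.30 for proteases, all 3 reversed, and 0.0512 for the cell cycle, 0.34 for immediate-early genes and -0.77 for PDGF receptors. For day 7 against intact they were 0.11 for the cell cycle, -0.16 for Notch genes, reversed, and -1.45 for PDGF receptors. For day 21 against day 7 they were -0.0131 for the cell cycle, -0.19 for matrix and 0.54 for PDGF receptors. The mixture values against intact nerve rest in part on 7 dividing, 16 MES_DIFF and 1 MES_EPI-diff cells of the intact library.

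With each cell weighted alike the cell cycle was at 3.87 for day 7 and 2.15 for day 21 against intact and -1.71 between them, Notch genes at 1.15 for day 21 against intact, and PDGF receptors at -1.57 for day 21 against intact and 0.20 against day 7. With thinned cells the cell cycle was at 3.47 for day 7 and 1.87 for day 21 against intact, PDGF receptors at 0.25 for day 21 against day 7, and retinoid genes in endoneurial cells at -0.0703, reversed. With size factors PDGF receptors were at 0.23 for day 21 against day 7. Without the dividing class the cell cycle was at 0.50 for day 21 against intact and -1.68 against day 7, and Notch genes at 1.08 for day 21 against intact.

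Over every barcode contractile genes were at -2.78 for day 7 against intact, reversed, and -0.70 for day 21 against day 7. Also reversed were interferon genes at 0.14 for day 21 against day 7, lipid genes at 0.00302 for day 21 against intact, and Notch genes at -0.86 for day 7 and -0.10 for day 21 against intact. PDGF receptors were at 0.23 for day 21 against day 7. Summed CPM over every barcode in intact nerve, day 7 and day 21 were 683, 605 and 772 for pericyte markers, 6339, 821 and 583 for vascular smooth muscle markers, 271, 152 and 312 for endothelial markers, 54.7, 413 and 6001 for Schwann markers, 71.6, 1221 and 927 for myeloid markers, 1.39, 2.44 and 2.62 for lymphocyte markers and 1752, 204 and 339 for erythroid markers. At day 7 and day 21 they were 2.68 and 50.5 for neutrophil and mast cell, 4.75 and 6.69 for adipocyte, 9.17 and 7.69 for skeletal muscle, and 58.7 and 41.5 for tenocyte and chondrocyte markers.

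Without cells under the thinning depth, endoneurial cells were 44.3% and epineurial cells 45.1% of intact cells, and perineurial cells 48.4% at day 21. Classes from clustering gave 8.65% endoneurial, 21.1% epineurial and 1.40% perineurial cells at day 7, and 27.4% epineurial and 57.9% perineurial cells at day 21. Over every barcode clustering gave endoneurial shares of 40.2%, 12.7% and 6.64%, epineurial shares of 30.2%, 10.5% and 17.1%, and perineurial shares of 2.60% at day 7 and 33.2% at day 21. Without the highest doublet scores the dividing class was 2.23% at day 21. Cycling shares for intact nerve, day 7 and day 21 were 3.43%, 49.2% and 7.49% unthinned, 10.4%, 34.5% and 13.8% with at least 1 UMI, and 0.447%, 13.9% and 2.94% with at least 3. Without the Schwann-like and pericyte-marker clusters they were 15.2% at day 7 and 2.70% at day 21.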

Other observations

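The barcodes without a class held other cell types along with mesenchymal-like cells, and the values in this and the next paragraph were picked after being seen. Of those that passed the UMI, gene and mitochondrial limits, Schwann-like barcodes were 5 of 343 in intact nerve, 281 of 1500 at day 7 and 1423 of 2296 at day 21. Pericyte-like barcodes numbered 45, 201 and 283, with Pdgfrb at 3203, 1831 and 2626 CPM. Endothelial-like barcodes numbered 28, 79 and 174, and myeloid-like barcodes 2, 175 and 175. Vascular smooth muscle-like barcodes numbered 199, 13 and 54. As the totals differ, shares read differently from numbers. Vascular smooth muscle-like shares were 58.0%, 0.867% and 2.35%, pericyte-like shares 13.1%, 13.4% and 12.3%, and endothelial-like shares 8.16%, 5.27% and 7.58%. Injury-like barcodes numbered 1, 224 and 9, endoneurial-like 25, 99 and 30, epineurial-like 38, 99 and 109, and perineurial-like 0, 2 and 23.

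Tendon genes were higher in the MES_EPI-diff class than in the epineurial class, some at day 7 and all of those measured at day 21. Tnmd, which encodes tenomodulin, was at 345 CPM at day 7 (94 cells) and 2058 at day 21 (22 cells), against 40.1 and 15.4 in the epineurial class. Scx was at 140 and 512 CPM against 3.47 and 0.679, Fmod at 152 and 1111 against 68.9 and 25.04, and Thbs4 at 1855 and 6094 against 385 and 193. Chodl was at 22.5 and 573 CPM against 1.92 and 0.291, and Col12a1 at 1159 and 1367 against 355 and 119. Comp (26.03 CPM against 20.6), Mkx (6.12 against 4.87) and Kera (2.04 against 1.33) differed little at day 7, and at day 21 they were at 118 against 4.47, 26.7 against 0.971 and 80.2 against 0.388.

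Of the tests below, those of free RNA and of reporter-negative cells were chosen after the results were seen, and the others had predictions written first, with the exceptions stated.

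Schwann transcripts in the dividing class lay in a Schwann-like cluster of 80 cells with Sox10 at 201 CPM against 2.15 in the other dividing cells. Free RNA would give other classes a similar level, but the dividing class had 7.74 times their level at day 21 (7.40 to 8.10). TdTomato, at 0.813 times that of the other dividing cells (0.622 to 1.05), speaks against single cells that lack the reporter. It cannot speak against Schwann cells without the reporter that were joined to a reporter-positive cell in a doublet. For doublets, the measure planned first, the level of Col1a1, Col3a1, Dcn and Pdgfra relative to the other dividing cells, was 0.474 (0.463 to 0.484), on the side that doublets predict, but Schwann-like barcodes without a class stood at 0.369 as well, so it separates little. A second measure with Dcn, Lum and Pdgfra, chosen after the first was seen, used the endoneurial, epineurial, perineurial and MES_DIFF classes of the same library. It gave from 0.0256 to 0.0911 of their levels (0.0838 to 0.0988 for the highest), which argues against doublets with cells of these classes. MES_EPI-diff cells and the other dividing cells were not compared by this measure, so doublets with them are not addressed. As its genes were picked after the planned measure came out on the other side, doublets stay open, and dividing Schwann-like cells of the Pdgfrb lineage may be present.

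Junction genes in the perineurial class were at -0.79 for day 21 against intact (-1.72 to 0.31 over members), and 3 technical explanations were tested. Thinned cells gave -0.92 (-1.67 to -0.19), with the upper end over members above the limit set beforehand for excluding depth per cell. Thinning leaves the expected proportions of genes within a cell unchanged. It changes only the weight of deep cells and leaves out shallow ones, so this test cannot decide on depth. The median depth of perineurial cells was 5291 UMIs in intact nerve and 5829 at day 21. The median was -0.60 with the day 21 cells of lower immediate-early share (-1.82 to 0.17), which leaves a stress response open, since these cells still had a median share of 0.535% against 0.206% in intact cells, and -0.44 within the cluster that held most intact perineurial cells (-1.39 to -0.12, 41 and 82 cells, 16 measured members in place of 20), which leaves the mixture of clusters open. Counting-error intervals, -1.32 to -0.50 for depth, -1.17 to -0.467 for stress and -0.82 to -0.27 for the mixture, were tried only after the first values were seen and were not used to decide. The bead step differs with the group and stays open, and so does the time after injury, as an untested hypothesis.

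Smooth muscle transcripts in the intact perineurial class had Acta2 at 16.2 times its level in endoneurial and epineurial cells (13.8 to 19.04), which free RNA would not give. The Myh11 to Acta2 count ratio was 0.0377 of that in smooth muscle-like barcodes (0.0103 to 0.0967), against doublets with, or misnaming of, smooth muscle cells. Of 116 cells, 42 had an Acta2 UMI, and 12 cells held 78.7% of these UMIs. Other smooth muscle genes were mixed. Tagln was at 1405 CPM against 32.9 in endoneurial and epineurial cells, and Myl9 at 516 against 88.4. Myh11 was at 5.52 against 10.1, and Cnn1 and Des had 0 counts in the perineurial class. Whether the perineurial class of intact nerve includes a few contractile cells is left open, and no biological explanation was tested.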
